A study of Mus musculus with 7 samples.

How the data were processed

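Poly(A)-selected, strand-specific libraries were made from 1 µg of total RNA with a TruSeq-style protocol and sequenced as 150-bp paired-end reads on a NovaSeq instrument, per the labels' protocols. The deposited table holds raw gene counts, whole numbers per Ensembl gene ID, for 7 libraries, and the authors' counts were used as deposited. The genome build GRCm39 and the tool DESeq2 1.38.0 are named in the submitters' processing notes. The aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here. The values are not scaled, since library totals differ, and no row lacks a gene ID. Every column of the table was matched to a sample through the column name in that sample's description. A further sample that the table's name refers to was not analysed here.

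Groups were taken from the treatment label, with 3 libraries for cecal slurry and 4 for vehicle, all at 24 h, and replicates carry the sample numbers of the labels. The groups share no sample number, so no pairing applies. The labels give liver as the tissue and wild type C57BL/6J as the background. The series title speaks of mice, while the sample titles and protocol fields speak of plated cells and of lipopolysaccharide doses, and this disagreement could not be settled from the labels. The titles also carry the words shSepsis and shControl and, in the vehicle group, a suffix after the sample number, and what these stand for is not given in the sources used here. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom 22.0 to 71.8), so each library counts once.

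The table has 56748 gene rows. Symbols were found for 52073 of them in a table of mouse gene names, and the other 4675 are named by their ID. Where several IDs share a symbol, the ID with the most counts keeps it. The reference tables in hand belong to an older mouse build than the counts, so no coordinates are given.

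Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15), which left 13589. Libraries were scaled by TMM, dispersions were estimated with robust moderation, and cecal slurry was compared with vehicle by glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes, and shares of counts use the unscaled totals. Log2 CPM for the principal components had a prior count of 2. Where a group had no count of a gene, the fold is given against a floor of 3 counts per library, which is 0.222 CPM with vehicle and 0.233 CPM after slurry. Where it had 1 to 3 counts, the ratio of summed counts is given with an exact 95% binomial interval. PCR duplicates are not marked by molecular identifiers, so floors and intervals cover counting error only.

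Before the data were examined, 49 gene lists were fixed (32 on liver biology and inflammation, 12 of cell type markers and 5 technical), as were the tests, the alternatives and the rule for named genes. Some genes stand in several lists, such as Hp, Ass1 and Glul. Lists with at least 5 tested members, 46 in all, were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists, and again with a correlation estimated per list, and with fry. The rule named the 6 genes with the largest rise and the 6 with the largest fall among genes called, at a mean of at least 10 CPM and without overlap between the groups. It also named, per list, the called member with the highest expression and the one with the largest change at a mean of at least 1 CPM, the most expressed member that went against the majority, and a short set of liver and sepsis genes. This gave 113 genes, of which the text prints a part. Further list members were named as examples after their values were seen. Summaries of each library (7 in all) were compared by an exact permutation test over 35 regroupings, two-sided on the absolute difference of means, whose smallest possible p is 0.0286.

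The procedure was tested on simulated counts for the 13589 genes of this comparison, with 200 genes changed. It called 31% of the 2-fold and 81% of the 4-fold genes in the right direction, 9 of 13007 unchanged genes, and none of 40 unchanged lists. Far more genes, 6425, were called in the real comparison, so these percentages need not hold for it. Genes were simulated independently and the unchanged lists held random genes, so the result for lists does not cover correlation between genes. In the real lists the estimated correlation reached 0.726.

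Alternatives were other scalings (RLE, upper quartile, total counts alone, library sizes without the 20 most abundant genes), no low-count filter or a filter of 1 CPM in 3 libraries, no robust moderation, limma-voom (limma 3.58.1), DESeq2 1.42.0, an adjusted p under 0.01, glmTreat against a fold of 1.5, log2 shares, all genes in the principal components, and leaving out each library in turn. A neutrophil list without Hp, shares of that list and hemoglobin ratios without each library, and the counts without both vehicle 20 and slurry 14, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.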

Results

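RNA from mouse liver of the C57BL/6J strain was sequenced 24 h after cecal slurry or vehicle. Cecal slurry is a suspension of the contents of the cecum, and the labels describe the exposure as a model of conditions like sepsis. The comparison asks which liver transcripts differ after that exposure. There were 3 cecal slurry libraries, named here slurry 4, 13 and 14, and 4 vehicle libraries, named vehicle 2, 8, 9 and 20. Total gene counts ranged from 11935857 in vehicle 20 to 14340250 in slurry 13, and the group means differed by less than the spread between libraries (exact permutation p = 0.343). The tissue label is liver, but the protocol fields also describe plated cells, so the text speaks of liver libraries. The labels do not say that each library came from its own animal, and the p-values below then measure only the spread between these libraries, which may be technical.

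After cecal slurry the libraries held far more RNA of acute phase proteins, inflammatory mediators and neutrophil markers, and far less RNA of hepatocyte enzymes and transporters. Genes of the acute phase list made up 28.9 ± 1.82% of all counts (SD, n = 3) against 5.14 ± 0.296% (SD, n = 4) with vehicle. Saa1, a serum amyloid A gene, rose from 3745 ± 1195 to 34565 ± 6758 CPM (counts scaled to library size), and Lcn2, which encodes an iron-sequestering lipocalin, rose from 353 ± 171 to 17044 ± 2683 CPM. Of 27 genes of the cytochrome P450 list 25 fell and 1 rose (adjusted p = 0.154 with an estimated correlation), with Cyp3a11 at 976 ± 508 CPM with vehicle and 51.0 ± 26.9 CPM after slurry. Of 14 markers of Kupffer cells, the resident macrophages of the liver, 8 fell and 1 rose (adjusted p = 0.556 with an estimated correlation), and of 17 markers of sinusoidal and other endothelium 11 fell and 2 rose (adjusted p = 0.196 with an estimated correlation). Those that fell included Clec4f, from 138 ± 36.9 CPM to between 13.3 and 34.3 CPM in the slurry libraries, and Clec4g, from 56.8 ± 2.46 to 1.55 ± 0.261 CPM.

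Of 13589 genes tested, 3009 were higher and 3416 lower after cecal slurry at an adjusted p under 0.05 in edgeR's quasi-likelihood test. Together these were 47.3% of the genes tested. At least 2-fold changes were found in 1807 of the genes that were higher and in 2432 of those that were lower. Principal component analysis of the 500 most variable genes placed 90.6% of the variance on a first component that separated the groups. Vehicle libraries lay between -50.30 and -41.40 on it, and slurry libraries between 60.95 and 64.31. Vehicle 20 lay apart from the other vehicle libraries on the second component, at 18.34 against -9.78 to 0.11. Spearman correlations of log2 CPM across genes were 0.964 to 0.982 between vehicle libraries, 0.952 to 0.973 between slurry libraries and 0.819 to 0.844 between the groups; genes are not independent replicates in these values.

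**Figure D1:**
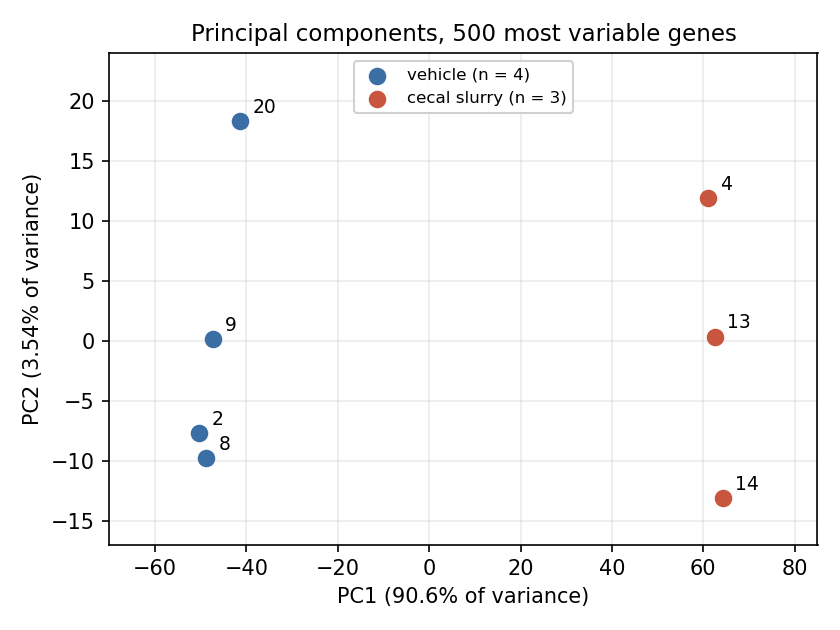
Position of each library (labelled by its sample number) on the first and second principal components of log2 CPM of the 500 most variable genes, with the percent of variance on each axis. The 4 vehicle libraries (blue) lie at -50.30 to -41.40 and the 3 cecal slurry libraries (orange) at 60.95 to 64.31 on the first component.

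The makeup of the libraries shifted with treatment. The 10 most abundant genes of each library took 14.7 to 15.5% of counts in the vehicle libraries and 24.9 to 29.1% in the slurry libraries, and genes of the mitochondrial genome took 6.04 ± 0.644% and 3.10 ± 0.281%. For both shares, and for the acute phase share, every slurry library lay beyond every vehicle library (exact permutation p = 0.0286, the smallest that 35 regroupings allow, adjusted p = 0.05 over 7 summaries). Albumin (Alb) took the largest share of counts with vehicle, at 2.75 ± 0.267%. After slurry the largest shares were those of Hpx, which encodes the heme carrier hemopexin, at 4.97 ± 0.314%, and Hp, which encodes haptoglobin, at 3.48 ± 0.126%. Next came the near-identical genes Saa1 at 3.25 ± 0.717% and Saa2 at 3.02 ± 0.627%. Shares of counts are not scaled for transcript length, so they do not rank transcripts by number of molecules. The number of genes detected did not differ by more than the spread, with 17650 ± 741 against 17301 ± 798 (exact permutation p = 0.6). Hemoglobin transcripts took 0.00671 ± 0.00215% of counts with vehicle and 0.0273 ± 0.0259% after slurry (exact permutation p = 0.143), and slurry 14 was highest at 0.0550%.

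Among the 6 genes with the largest rises at a mean of at least 10 CPM were 4 that encode cytokines or chemokines. Csf3 (ENSMUSG00000038067), which encodes the neutrophil growth factor G-CSF, had no count with vehicle and averaged 187 ± 178 CPM after slurry, at least 844-fold higher against a floor of 3 counts per library. The chemokine gene Cxcl3 (ENSMUSG00000029379) was at least 299-fold higher and Il6 (ENSMUSG00000025746), which encodes the main inducer of the acute phase response, at least 123-fold higher. The Csf3 call (adjusted p = 0.0388) was lost without vehicle 20 (adjusted p = 0.0522), slurry 13 (0.155) or slurry 14 (0.0875), and that of Il6 (adjusted p = 0.0248) without slurry 13 (0.0936). Both were also lost without a low-count filter and in limma-voom. Their levels differed between the slurry libraries, with 29.7 CPM in slurry 4, 152 in slurry 13 and 380 in slurry 14 for Csf3, and 5.23, 26.8 and 49.8 CPM for Il6. Cxcl2 (ENSMUSG00000058427) rose by a log2 fold change of 11.70 ± 1.23 (SE) and the protease inhibitor gene A2m (ENSMUSG00000030111) by 9.99 ± 0.94. Without vehicle 8 these were 12.69 and 11.37, and Cxcl2 was at 10.86 without slurry 14. The Cxcl2 call was lost in limma-voom (adjusted p = 0.0803). The gene ENSMUSG00000121249, for which no symbol was matched, had 2 counts with vehicle and 6919 after slurry, a ratio of 4854 with a 95% counting interval of 1343 to 40090.

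The largest falls included those of enzymes of liver metabolism. Hsd3b2 (ENSMUSG00000063730), a hydroxysteroid dehydrogenase gene, had no count after slurry and was at least 127-fold lower. Keg1 (ENSMUSG00000024694) had 8145 counts with vehicle and 1 after slurry, a ratio of 5805 with a 95% counting interval of 1042 to 229300, and Etnppl (ENSMUSG00000019232) had 2495 and 2, a ratio of 889 (246 to 7346). Hsd3b5 (ENSMUSG00000038092) fell by 8.71 on the log2 scale (SE 0.66), Cyp7a1 (ENSMUSG00000028240), the rate-limiting enzyme of bile acid synthesis, fell by 8.63 (SE 0.53), and Dpys (ENSMUSG00000022304), an enzyme of pyrimidine breakdown, fell by 7.74 (SE 0.65). Without slurry 14 Hsd3b5 was at -9.51 and Dpys at -8.66. The counts after slurry were all in slurry 14 for Keg1 and all in slurry 13 for Etnppl and Cyp7a1. Without that library no count was left, and the fitted values were -13.94 for Keg1, -12.22 for Etnppl and -12.20 for Cyp7a1. With all libraries the adjusted p-values in this paragraph were at most 7.28e-05. Intervals and floors cover counting error only, and fitted fold changes of genes with no count in a group are not bounds.

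**Figure D2:**
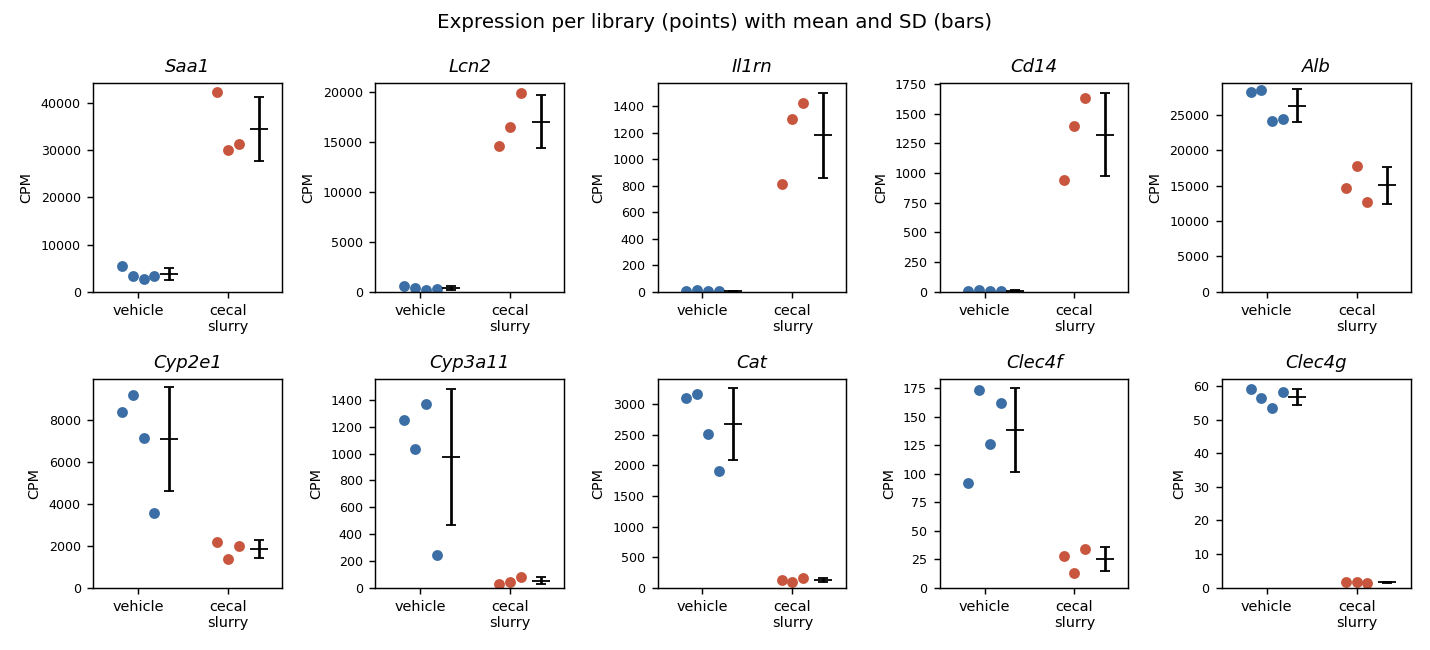
CPM of 10 genes in each library (points; blue vehicle, n = 4, orange cecal slurry, n = 3), with the group mean and SD as bars, on linear axes that start at 0. Slurry libraries lie above all vehicle libraries for Saa1, Lcn2, Il1rn and Cd14, and below them for Alb, Cyp2e1, Cyp3a11, Cat, Clec4f and Clec4g.

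Plasma protein genes moved apart. Of the 26 acute phase genes, 23 rose and 1 fell, with a median log2 fold change of 2.42 (camera adjusted p = 2.01e-18, and adjusted p = 0.0562 with an estimated correlation). Hpx rose by 2.25 ± 0.15, and Il1rn, which encodes the antagonist of the interleukin-1 receptor, by 8.03 ± 0.56. Crp, the gene of C-reactive protein, was the member that fell, at -1.40 ± 0.19. The iron hormone gene Hamp stood at 1.55 ± 0.66 and did not pass the test (adjusted p = 0.102), but passed without vehicle 9 (adjusted p = 0.0481) or slurry 4 (0.0201), in DESeq2 (0.0439) and without robust moderation (0.0276). Of 25 other secreted hepatocyte proteins, 14 fell and 1 rose (camera adjusted p = 0.00556, and adjusted p = 0.215 with an estimated correlation). Alb fell by 0.81 (SE 0.17) and Igfals, which encodes the stabilizing subunit of circulating insulin-like growth factor, fell by 4.22 (SE 0.24), while Trf, the transferrin gene, rose by 0.94 ± 0.18. Among 22 complement genes 13 fell and 3 rose, with C3 up by 0.87 ± 0.20, and among 27 genes of coagulation and fibrinolysis 13 fell and 6 rose. The heparin cofactor gene Serpind1 fell by 4.06. Neither list passed its own test (camera adjusted p = 0.068 for complement and 0.152 for coagulation), though both did in limma-voom (0.00979 and 0.00994) and complement with total counts alone (0.0449) and without a low-count filter (0.0139). Adjusted over the list alone, 14 complement and 15 coagulation genes fell, and the other counts in this paragraph were the same.

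In the list of cytokines and chemokines 17 of 24 genes rose and none fell (camera adjusted p = 2.72e-10, and adjusted p = 0.154 with an estimated correlation), among them Cxcl1 by 5.47 ± 0.69 and Il1b by 3.97 ± 0.60. Of 28 targets and regulators of NF-kB and STAT3, 26 rose and 1 fell (camera adjusted p = 9.58e-18, and adjusted p = 0.148 with an estimated correlation). Tnfaip3, a feedback inhibitor of NF-kB, rose by 7.02 ± 0.89 and Sod2, the mitochondrial superoxide dismutase gene, by 2.55 ± 0.19. Tnfaip3 was at 6.16 without slurry 14. The member that fell was Il6st, at -0.42 ± 0.16 (adjusted p = 0.0457), a call lost without any 1 of the 7 libraries (adjusted p = 0.0587 to 0.126) and under each scaling alternative except total counts. In microbial sensing 11 of 26 genes rose and 3 fell (camera adjusted p = 0.00577, and adjusted p = 0.196 with an estimated correlation). Cd14, a co-receptor for lipopolysaccharide, rose by 7.51 ± 0.48, and Irak1 fell by 0.56 (SE 0.15). Of 17 enzymes of arginine, tryptophan and itaconate metabolism, 8 rose and 4 fell, or 2 without slurry 4 (camera adjusted p = 0.0178, and adjusted p = 0.154 with an estimated correlation). Ptgs2 was at least 73.1-fold and Nos2, the inducible nitric oxide synthase gene, at least 57.1-fold higher, each from no count with vehicle, whereas Ass1 fell by 1.96 (SE 0.30). Among 33 interferon-stimulated genes 6 rose, 1 fell and 26 did not pass the test (camera adjusted p = 0.241). Zbp1 rose by 2.21 ± 0.29 and Gbp2 by 2.22 ± 0.35. The median of this list was 0.16, and -0.01 with total counts alone, and without slurry 4 the list passed as higher (adjusted p = 0.00596), with 11 genes higher. The number lower was 2 without vehicle 2, slurry 13 or slurry 14, and 3 with total counts alone. Of 19 antigen presentation genes 6 fell and 3 rose (camera adjusted p = 0.542), with B2m at -1.20 ± 0.19, Ciita, the activator of class II genes, at -3.21 ± 0.83 (-4.27 without slurry 13) and H2-D1 at 0.69 ± 0.16. Adjusted over the list alone, 4 interferon-stimulated genes and 11 enzymes of the arginine list rose, and the other counts in this paragraph were the same.

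**Figure D3:**
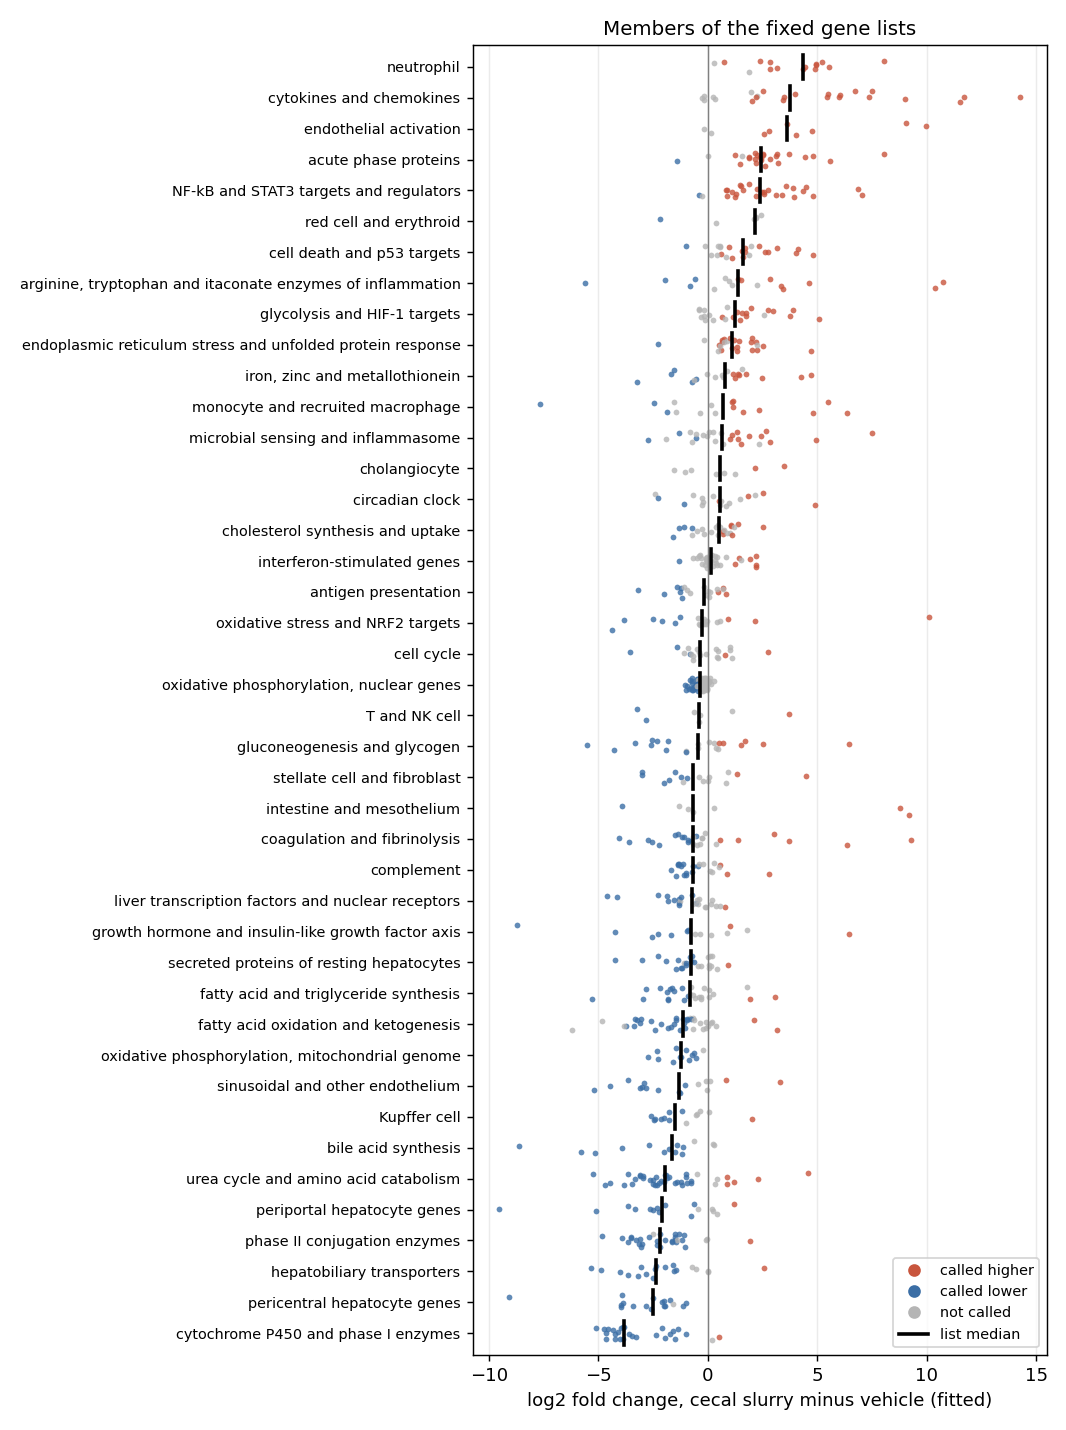
Fitted log2 fold change (cecal slurry minus vehicle) of each tested member of the gene lists on biology and cell type markers with at least 5 tested members, with 1 line per list, ordered by the list median (black bar). Points are orange where the gene was called higher, blue where lower and grey where not called; medians run from -3.82 in the cytochrome P450 list to 4.36 in the neutrophil list.

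Most genes of the drug and bile acid metabolism lists fell. Of 27 cytochrome P450 and other phase I genes, 25 fell and 1 rose, with a median of -3.82 (camera adjusted p = 6.2e-14, and adjusted p = 0.154 with an estimated correlation). Cyp2e1 fell by 1.94 (SE 0.32) and Cyp2f2 fell by 5.09 (SE 0.32). Por, the electron donor of these enzymes, was the member that rose, by 0.53 ± 0.19 (adjusted p = 0.037). That call was lost without vehicle 9 (adjusted p = 0.108) or 20 (0.0855), slurry 13 (0.145) or 14 (0.0814), and with total counts alone (0.126). Among 31 phase II conjugation enzymes 26 fell and 1 rose, the methyltransferase gene Nnmt by 1.92 ± 0.20 (camera adjusted p = 1.95e-09, and adjusted p = 0.154 with an estimated correlation). In bile acid synthesis 11 of 14 genes fell and none rose (camera adjusted p = 2.73e-07, and adjusted p = 0.115 with an estimated correlation), among them Cyp8b1 at -5.78 and Scp2 at -1.17 ± 0.24. Of 19 hepatobiliary transporter genes 14 fell and 1 rose (camera adjusted p = 2.72e-10, and adjusted p = 0.115 with an estimated correlation). Slco1b2, which encodes an organic anion uptake carrier, fell by 5.33 (SE 0.25), Abcb11, the bile salt export pump gene, fell by 4.90, and Abca1, a cholesterol exporter gene, rose by 2.58 ± 0.18. Among 24 liver transcription factors and nuclear receptors 12 fell and 1 rose (camera adjusted p = 0.00867, and adjusted p = 0.193 with an estimated correlation). Cebpa fell by 1.86 (SE 0.17) and Nr1i3, which encodes the xenobiotic receptor CAR, fell by 4.62 (SE 0.52), while Rora rose by 0.79 ± 0.19. The number higher was 2 without vehicle 20 or slurry 14, in limma-voom and under each scaling alternative except total counts. Both zones of the lobule took part. Of 17 genes typical of hepatocytes around the central vein 16 fell, with Lgr5 at least 22.1-fold lower from 275 counts with vehicle to none (camera adjusted p = 8.87e-10, and adjusted p = 0.154 with an estimated correlation). Of 16 genes typical of hepatocytes around the portal vein 11 fell and 1 rose, Arg1 by 1.21 ± 0.18, with 2 higher without slurry 4 (camera adjusted p = 1.88e-05, and adjusted p = 0.154 with an estimated correlation). Adjusted over the list alone, 27 phase II genes fell, and 13 transcription factors fell and 2 rose; the other counts in this paragraph were the same.

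Genes of amino acid catabolism and fatty acid metabolism fell in larger number than they rose, while genes of cholesterol and glucose metabolism went both ways. Of 41 genes of the urea cycle and amino acid catabolism, 33 fell and 5 rose (camera adjusted p = 1.1e-11, and adjusted p = 0.148 with an estimated correlation). Cps1, the entry enzyme of the urea cycle, fell by 3.63, while Mat1a rose by 0.89 ± 0.19. In fatty acid oxidation and ketogenesis 21 of 38 genes fell and 2 rose (camera adjusted p = 0.000316, and adjusted p = 0.562 with an estimated correlation). The number higher was 1 without vehicle 8, slurry 13 or slurry 14, and without a low-count filter. Acaa1b fell by 3.74 (SE 0.86), and was at -4.87 without slurry 14. Cpt1a, the gatekeeper of mitochondrial fatty acid import, was at -0.08 ± 0.20 (adjusted p = 0.782). In fatty acid and triglyceride synthesis 13 of 27 genes fell and 2 rose (camera adjusted p = 0.00928, and adjusted p = 0.45 with an estimated correlation), with Elovl3 at -5.27 ± 0.88 (-4.62 without vehicle 9 and -5.96 without slurry 4) and the lipid droplet gene Plin2 at 1.95 ± 0.19. Of 24 cholesterol genes 7 rose and 4 fell (camera adjusted p = 0.28). The number higher was 15 without vehicle 20, 4 without vehicle 2, vehicle 9, slurry 13 or slurry 14, and 3 with total counts alone. Fdps rose by 2.53 ± 0.57, and by 3.42 without vehicle 20. Of 22 genes of gluconeogenesis and glycogen 9 fell and 6 rose (camera adjusted p = 0.0971), with Igfbp1 at 6.43 ± 0.90 (7.08 without vehicle 9) and Fbp1 at 1.69 ± 0.17. Pck1 was at -0.45 ± 0.46 (adjusted p = 0.465). In glycolysis and HIF-1 targets 13 of 24 genes rose and none fell (camera adjusted p = 4.54e-05, and adjusted p = 0.196 with an estimated correlation), among them Ldha by 1.48 ± 0.17 and Pfkfb3, which encodes an activator of glycolysis, by 5.08 ± 0.32. Without slurry 14 4 genes of this list were lower, with total counts alone 2 and in limma-voom 1. Of 13 mitochondrial genome genes 12 fell, among them mt-Co1 at -0.84 ± 0.17, with a median of -1.23 (camera adjusted p = 0.00422, and adjusted p = 0.45 with an estimated correlation). Of 71 nuclear genes of oxidative phosphorylation 27 fell, with a median of -0.35 (camera adjusted p = 0.0318, and adjusted p = 0.785 with an estimated correlation). That list's call was lost without vehicle 2 (adjusted p = 0.081) or 9 (0.066), or slurry 4 (0.127) or 13 (0.0542). The number lower was 16 without vehicle 2, 14 without slurry 4 or without slurry 13, and 43 with total counts alone. Without vehicle 20 the cholesterol list passed the test as higher (adjusted p = 0.00208), and the gluconeogenesis list passed as lower without slurry 14 (0.00321) and without a low-count filter (0.0126). Adjusted over the list alone, 34 amino acid genes, 23 fatty acid oxidation genes and 26 nuclear oxidative phosphorylation genes fell and 14 glycolysis genes rose, and the other counts in this paragraph were the same.

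Stress genes rose in several lists. Of 25 genes of endoplasmic reticulum stress 18 rose and 1 fell (camera adjusted p = 2.78e-05, and adjusted p = 0.196 with an estimated correlation). Hspa5, the main chaperone of that compartment, rose by 1.95 ± 0.24, and Ern1, which encodes the stress sensor IRE1, fell by 2.26 (SE 0.18). Of 24 cell death and p53 genes 14 rose and 1 fell (camera adjusted p = 9.01e-06, and adjusted p = 0.154 with an estimated correlation). Those that rose included the cell cycle inhibitor gene Cdkn1a, by 4.79 ± 0.41, and the survival gene Mcl1, by 0.61 ± 0.15, and the death gene Bbc3 fell by 0.98 (SE 0.28). Of 12 immediate early genes 11 rose (camera adjusted p = 1.39e-07, and adjusted p = 0.196 with an estimated correlation), with Ier3 up by 8.25 ± 0.45 (7.62 without slurry 14). Among 55 cytosolic ribosomal protein genes 31 rose and none fell, with a small median of 0.47 (camera adjusted p = 0.000295, and adjusted p = 0.556 with an estimated correlation). With total counts alone 20 of them were called higher and the median was 0.32. Of 10 heat shock genes 5 fell, among them Hspa1b at -2.93 ± 0.51, and 1 rose, or 2 without a low-count filter (camera adjusted p = 0.184). In the iron, zinc and metallothionein list 8 of 20 genes rose and 5 fell (camera adjusted p = 0.0516), with Mt2 up by 4.69 ± 0.77 (6.10 without vehicle 20) and Fth1 up by 1.14 ± 0.24. That list passed as higher without vehicle 9 (adjusted p = 0.03) or 20 (0.00721), or slurry 13 (0.0351). It also passed with upper quartile scaling (0.0475), total counts alone (0.0411), no low-count filter (0.0177), no robust moderation (0.0402) and limma-voom (0.038). The number lower was 3 without vehicle 2, vehicle 9 or slurry 13, and 2 without vehicle 8 or slurry 14. Of 20 NRF2 and oxidative stress genes 6 fell and 3 rose, and with total counts alone 10 fell (camera adjusted p = 0.413). The catalase gene Cat fell by 4.40 (SE 0.26), and Slc7a11, a cystine importer gene, was at least 46.3-fold higher from no count with vehicle. In the growth hormone list 7 of 14 genes fell and 2 rose (camera adjusted p = 0.0505), with Igfbp4 at -0.93 ± 0.16. It passed as lower without vehicle 2 (adjusted p = 0.0417), 8 (0.041) or 20 (0.0363), or slurry 13 (0.0476) or 14 (0.05). It also passed with RLE (0.0491), upper quartile scaling (0.0449), library sizes without the 20 most abundant genes (0.0467) and no low-count filter (0.0255). Among 18 clock genes 4 rose and 2 fell (camera adjusted p = 0.164), with Per1 up by 4.89 ± 0.31 and Hlf at -1.10 ± 0.17. The number lower was 4 without vehicle 9, and 1 without vehicle 2, in limma-voom or without any 1 slurry library, and 7 were higher without a low-count filter. Of 21 cell cycle genes 3 fell and 2 rose (camera adjusted p = 0.919). The test's direction for this list was up, while its median was -0.33 and its mean -0.14. In it 1 gene fell without vehicle 9, slurry 13 or slurry 14, and 1 rose without vehicle 2, 8 or 9, or slurry 4 or 14, or with total counts alone, and without a low-count filter 1 gene went each way. Adjusted over the list alone, 20 endoplasmic reticulum, 12 immediate early, 33 ribosomal, 9 iron and 3 clock genes rose, and for the cell cycle 1 gene rose and 1 fell; the other counts in this paragraph were the same.

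Markers of the cell types of the liver moved in different directions. Of 15 neutrophil markers 13 rose and none fell (camera adjusted p = 1.04e-08, and adjusted p = 0.154 with an estimated correlation), with S100a8 up by 5.23 ± 0.45 and the granule gene Ngp by 8.06 ± 1.07, the latter not called in limma-voom (adjusted p = 0.0721). Without slurry 4 these were 4.58 and 6.88, and Ngp was at 9.08 without vehicle 2. This list holds Hp, which hepatocytes express, and without it 12 of 14 markers rose and their share of counts went from 0.00223 ± 0.000551% to 0.0288 ± 0.0178% (exact permutation p = 0.0286), or to 0.0185% without slurry 4. Of 14 Kupffer cell markers 8 fell and 1 rose (camera adjusted p = 0.0178, and adjusted p = 0.556 with an estimated correlation). Cd5l fell by 2.58 (SE 0.46) and Clec4f fell by 2.47 (SE 0.35), while the scavenger receptor gene Marco rose by 2.00. Among 16 monocyte and recruited macrophage markers 8 rose and 3 fell (camera adjusted p = 0.164), with 5 higher without slurry 4 and Cx3cr1 at least 8.12-fold lower, with no count after slurry. Of 17 endothelial markers 11 fell and 2 rose (camera adjusted p = 2.77e-05, and adjusted p = 0.196 with an estimated correlation). Clec4g fell by 5.19 (SE 0.21), while Lyve1 rose by 3.29. Endothelial activation genes rose in 7 of 9 cases (camera adjusted p = 1.91e-08, and adjusted p = 0.115 with an estimated correlation), among them Selp, the P-selectin gene, by 4.76, and Ch25h went from 2 counts to 1817, a ratio of 1275 (95% counting interval 352 to 10530), with both vehicle counts in vehicle 9 and a fitted log2 fold change of 9.98, or 12.30 without it. Of 16 stellate cell and fibroblast markers 7 fell and 2 rose (camera adjusted p = 0.184), with Timp1 up by 4.47 ± 0.46. Of 8 cholangiocyte markers 2 rose (camera adjusted p = 0.293), with Sox9 up by 3.48 ± 0.42. The number higher was 1 without vehicle 2, vehicle 9 or slurry 13 and with total counts alone, and 1 was lower without slurry 4. Of 7 T and NK cell markers 2 fell and 1 rose (camera adjusted p = 0.982). The number lower was 0 without vehicle 2, 9 or 20, or slurry 14, and 1 without slurry 4 or 13, with upper quartile scaling, the filter of 1 CPM or limma-voom. Of the 4 B cell genes tested none passed in edgeR, and 1 was lower without slurry 14, without a low-count filter, in limma-voom and in DESeq2. The red cell list had 1 of 6 genes lower, Alas2, and none higher (camera adjusted p = 0.841). It passed as higher without slurry 13 (adjusted p = 0.019), with 4 genes higher, and 4 were higher without robust moderation, 3 in DESeq2, and 1 with upper quartile scaling, library sizes without the 20 most abundant genes or the filter of 1 CPM. In the list of intestine and mesothelium 2 of 7 genes rose, Reg3g by 9.21 ± 0.55 and Reg3b by 8.80, and 1 fell (camera adjusted p = 0.25); its test pointed up with a median of -0.67 and a mean of 1.64, and it passed as higher without slurry 14 (adjusted p = 0.00804), while 2 were lower without slurry 4. Cela1 was the pancreas gene that passed the filter, and it fell by 2.16 (SE 0.39). Among nuclear-retained RNAs 1 of 5 was higher, Kcnq1ot1 by 1.81 ± 0.49, and 2 without vehicle 20 or without a low-count filter (camera adjusted p = 0.447), and among Y-linked genes and Xist 2 of 4 were higher, among them Ddx3y by 1.05 ± 0.18, which had counts in every library. Adjusted over the list alone, 9 Kupffer cell markers fell, 3 stellate markers rose and 8 fell, 1 cholangiocyte marker rose and 3 genes of the Y-linked list rose, and the other counts in this paragraph were the same.

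Of 46 lists tested, 12 were called higher and 15 lower with the preset correlation of 0.01 between genes. None was called with an estimated correlation, where 14 had an unadjusted p under 0.05, while fry called 15 higher and 21 lower. List directions therefore rest on the gene counts given. Counts in 1 direction are to be read against the 3009 higher and 3416 lower of all 13589 genes tested. Together these were 47.3%. Some lists lay below that share of calls in either direction, such as interferon-stimulated genes with 6 higher and 1 lower of 33, and cholangiocyte markers with 2 higher of 8. Counts of near-identical or overlapping genes (Saa1 with Saa2, the Hsd3b genes, Gstp1, Hspa1b, mt-Atp8 with mt-Atp6, Kcnq1ot1 with the gene it overlaps) are uncertain, because how the authors' counting assigned shared reads is not given in the sources used here.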

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

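The tests of explanations in this part were chosen only after the results they concern had been seen; the check for a vehicle library far from the others was fixed before. Among 120 named genes and library summaries, 7 had 1 vehicle library whose gap to the nearest other took up most of the range of that group, and chance alone gives about 1 in 20. Vehicle 8 had 1.495 CPM of A2m, against 0.0775 to 0.280 in the other vehicle libraries. Vehicle 20 had 707 CPM of Crp (others 592 to 610), 10.9 CPM of Fdps (others 1.83 to 3.06), 5.12 CPM of Mt2 (others 0.483 to 0.747), 50.3 CPM of Ccnd1 (others 3.92 to 11.1) and 1173 CPM of Arg1 (others 1118 to 1127). Vehicle 9 had 0.161 CPM of Ch25h, and the other vehicle libraries had none.

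The 7 lists of hepatocyte enzymes, transporters and zones were called lower (adjusted p = 0.115 to 0.154 with an estimated correlation). A lower share of hepatocyte RNA was tested on markers of other cell types. Neutrophil markers without Hp changed by 4.79 log2 units more than Kupffer cell markers (SD between libraries 0.518, exact permutation p = 0.0286). That difference uses no gene of the hepatocyte lists, and other cell types can change apart from each other. It therefore cannot decide, and a lower hepatocyte share stays open. A few abundant genes taking most of the counts would shift all genes alike, and the pooled median of 7 such lists was -2.35 with total counts alone and -2.14 with library sizes that leave out the 20 most abundant genes, a shift of 0.21 that argues against this as the whole cause. A response of hepatocytes to the treatment is a further hypothesis, which was not tested. The labels disagree on whether the RNA came from tissue or culture. All 14 Kupffer cell and all 17 endothelial markers passed the low-count filter. With vehicle, Clec4f was at 138 ± 36.9 CPM and Clec4g at 56.8 ± 2.46 CPM, beside Cyp2e1 at 7056 ± 2477 CPM. These values argue against a culture of hepatocytes alone. They do not tell liver tissue from a culture of mixed liver cells, so that question stays open.

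Of 14 Kupffer cell markers 8 fell and 1 rose, of 17 endothelial markers 11 fell and 2 rose, and of 15 neutrophil markers 13 rose (adjusted p = 0.556, 0.196 and 0.154 with an estimated correlation). Fewer endothelial cells would lower their markers alike only if no other cell type expressed them and their expression per cell stayed the same. The SD of the members' log2 changes was 2.13 against a median SE of 0.220, with members called in both directions. Kupffer cell markers also varied, with an SD of 1.26 against 0.360 and members called in both directions. The markers of each list thus did not fall alike. Neither condition was tested, so the spread cannot decide, and loss of cells stays open. For neutrophils of blood left in the tissue, the hemoglobin share was 4.07 times higher after slurry on average (exact permutation p = 0.143), but 1.99 times without slurry 14, and slurry 13 lay below all vehicle libraries, so recruited and circulating neutrophils cannot be told apart. No sort or wash that would remove blood is given in the labels.

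Reg3g and Reg3b rose together from 0.958 to 519 ± 291 CPM (SD, n = 3). Both are abundant in intestine and pancreas, so tissue carried over at collection was tested on 11 other genes of each tissue with under 0.5 CPM with vehicle. The rise of the intestinal genes, from 0.175 to 0.217 CPM in sum, was 0.00806% of that of Reg3g and Reg3b, and the rise of the pancreatic genes, from 0 to 0.194 CPM, was 0.0376%. Both values argue against carry-over, and expression in liver cells may be the source, as a hypothesis.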

How the results depend on the processing

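The neutrophil list without Hp, its share and the hemoglobin ratio without each library, and the removal of 2 libraries together were chosen after seeing the data; the other alternatives were fixed before. No named gene or list that was called took the opposite call under any alternative. Across scalings, filters, moderation and tools, 2396 to 3285 genes were higher and 3271 to 3898 lower, with the lowest count of higher genes under total counts alone, which shifted the median log2 fold change of all genes to -0.17. At an adjusted p under 0.01 the counts were 2076 and 2436. Tested against a fold of 1.5 with glmTreat they were 1667 and 2236, as that test asks for more than a difference from 0. Leaving out a library gave 2432 to 3006 higher and 2885 to 3473 lower, with 12 to 14 lists higher and 14 to 17 lower. Without vehicle 20 and slurry 14 together the counts were 2669 and 3147. With an estimated correlation, camera called 0 lists higher and 0 lower, while 14 had an unadjusted p under 0.05. The fry test called 15 higher and 21 lower. It asks whether a list's genes move 1 way on balance and, unlike camera, does not compare them with the other genes. As 47.3% of all genes tested were called, a fry call does not mark a list as different from other genes. Other causes of the difference between the tests were not tested. The first component held 73.3% of the variance with all genes past the filter. The exact tests of library summaries cannot reach 0.05 once a library is left out, with p of 0.0667 or 0.1. Genes with few counts in a group carry bounds or wide counting intervals.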

Other observations

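The gene families in this paragraph were chosen after their values were seen, and no family median changed sign under any scaling. Family counts are to be read against the 3009 higher and 3416 lower of all 13589 genes tested. Of 9 Serpina3 genes, which encode protease inhibitors, 8 rose, with a median log2 fold change of 3.17. All 6 Akr1c genes, 12 of 15 UDP-glucuronosyltransferase genes and 13 of 14 carboxylesterase genes fell, with medians of -3.71, -3.08 and -2.11. Of 19 major urinary protein genes 6 fell, and 6 to 9 across scalings, though near-identical members share reads. Of 55 translation initiation factor genes 25 rose and 4 fell, and 16 rose with total counts alone. Of 37 proteasome subunit genes 16 rose and 2 fell, with 8 to 19 higher across scalings. Of 10 Tmed genes, which carry cargo out of the endoplasmic reticulum, 7 rose and 1 fell. Of 78 mitochondrial ribosomal protein genes 28 fell and 8 rose, with 27 to 36 lower and 4 to 10 higher across scalings. Large single rises were those of Tifa, a signalling adaptor gene, from 27.4 ± 2.26 to 1598 ± 163 CPM, Crybb3 from 3.06 ± 2.39 to 426 ± 25.6 CPM, Lepr, the leptin receptor gene, from 2.19 ± 0.604 to 94.4 ± 37.9 CPM, and Slc10a6 from 0.110 ± 0.136 to 73.8 ± 6.45 CPM.

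All tests in this paragraph were chosen after results had been seen. Less food intake may lie behind part of the metabolic changes. Of 14 genes that fasting raises, 4 were lower (among them Ehhadh, G6pc and Acot1) and 3 higher (Igfbp1, Angptl4, Pdk4), and of 12 that it lowers 4 were lower and none higher, so less food intake as the whole cause cannot be told apart from other causes. The Angptl4 call was lost without vehicle 8 (adjusted p = 0.0561), slurry 13 (0.0785) or slurry 14 (0.0882), and without a low-count filter (0.0783). Of 18 genes with higher expression in male liver 14 fell. Among them were Keg1, Hsd3b2 and Hsd3b5, already named above for the largest falls, so this count is no independent support. A switch to the female liver program would raise female-biased genes, but of 9 tested (25 in the list) 4 were lower (Prlr, Abcd2, Fmo2, Atp6v0d2) and none higher. This argues against a full switch. A wide fall of hepatocyte genes could hide part of a rise, so a partial switch stays open.

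The 7 libraries can be split into 3 and 4 in 35 ways, the real one included. For genes called, 1 split was as large, the real one with 6425, and the highest other gave 2. For genes with at least a 2-fold change, 1 split was as large, the real one with 4239, and the highest other gave 2. For both counts the real split stood alone, a share of 1 in 35, or 0.0286, the smallest that these splits can give. That share treats the libraries as independent, which the labels do not state. For the number of lists called with the preset correlation, 5 splits gave as many as the real 27, and the highest other gave 28, so chance is not excluded for that number. Of the other 4 splits, 3 set 3 vehicle libraries against the rest and so keep the slurry libraries together, which carries part of the treatment difference. The remaining 1 set vehicle 20 with slurry 4 and 14 against the rest, which also carries part of it. No split into 3 and 4 balances the groups exactly, so lists called in the other splits are not free of treatment. Across all splits but the real one, 3 to 28 lists were called, though at most 2 genes were. Camera p-values at the preset correlation may therefore be too small, and those with an estimated correlation stand beside them above.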
